A study of Caenorhabditis elegans with 2 samples.

How the data were processed

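Chromatin immunoprecipitation with sequencing was done by the authors on whole L1 larvae of Caenorhabditis elegans that carry eGFP-tagged NHR-77, in 2 biological replicates. Per the labels, the replicates are separate biological samples of 1 strain and 1 group, and both were used. The deposited data used here are 8 peak lists, 4 per genome build (ce10 and ce11): 1 for each replicate, 1 for the replicates pooled, and 1 set to which the authors applied a threshold by IDR. IDR, the irreproducible discovery rate, is a measure of agreement between replicates, and this set is called the reproducible set here. Per the deposited notes, peaks were called on alignments against a control, the replicate and pooled lists were made as relaxed input for IDR and include background, and the reproducible set was derived from the pooled and both replicate lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and the control was not analysed here.

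The signal in each deposited list is the authors' value, taken here as the height of a peak against the control. Since the peak caller is not given, this reading is uncertain, and the signal was used only to rank peaks within a list. The −log10 q value of each peak in the deposited lists was used only to break ties, and 1090 of the reproducible peaks share its highest value of 3.34. The deposited lists also give the position of each summit. The 2285 reproducible ce11 peaks cover 2284 distinct intervals, because 1 interval is listed with 2 summits. Each of these intervals is in the pooled list, which holds 2285 peaks at or above the lowest signal of the reproducible set. The set thus matches the strongest peaks of the pooled list. Its name does not mean that each peak was found in both replicates, and 2279 of its regions held a peak in both replicate lists. Peak lists hold no read counts, so the depth is unknown and no value here could be corrected for it. Relaxed lists depend on depth and caller settings, so replicates were compared over equal numbers of their strongest peaks.

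Positions were read against the ce11 genome sequence (WBcel235, RefSeq) and the Ensembl annotation, release 115, for 6 nuclear chromosomes, and all ce11 peaks lie within the chromosome lengths. The ce10 lists were used only for counts and for replicate overlap, and no coordinates were converted. A gene was called bound when a summit lay from 1000 bp upstream to 250 bp downstream of its annotated 5' end. Shares have exact (Clopper-Pearson) 95% intervals. Peaks were taken as shared when they overlapped by at least 1 bp. Overlap and promoter share were set against 1000 random placements within each chromosome, with 20 placements for the overlap of the full lists. Gene lists, gene classes and chromosome regions were tested with Fisher's exact test, two-sided, and motifs with the exact McNemar test. Benjamini-Hochberg adjustment was made within each family of gene lists, gene classes and motifs. The p-values of chromosome regions were not adjusted. The threshold was 0.05 throughout. These tests take genes or windows as units, not samples, so their p-values do not measure the spread between animals, and the value from each replicate is given beside the main results. Neighbouring genes with overlapping windows can share a peak or its absence. They are not independent units, so the p-values of gene lists and gene classes, piRNA genes among them, may be too small. Lists and motifs were chosen, with the tests and most alternatives, before the data were examined.

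The text names genes by a rule fixed at the same time. It takes the genes with a promoter summit of one of the 25 strongest peaks found in both replicates, or the nearest start where there is none. It adds the 3 bound members with the highest signal of each list past the threshold, the 1 highest of every other list, nhr-77 and unc-119, and the 5 highest nuclear hormone receptors, since more than 12 were bound. Genes named outside it are the small RNA genes and xol-1 in the closing part, which were chosen after their values were seen.

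The alternatives were the ce10 lists, the 1143 strongest reproducible peaks, each replicate left out (the 2285 strongest peaks of the other one), narrow (500 bp upstream to 100 bp downstream) and wide (2000 to 500 bp) promoter windows, assignment to the nearest start only, other gene backgrounds, other motif windows (100 and 300 bp), motif controls matched on position and GC content (the best of 30 candidate windows each), and 10 or 40 kb around nhr-77 and unc-119. The alternatives added after the data were seen were small RNA classes outside promoters, promoters of all gene classes except piRNA, and lists stratified by 10 classes of promoter GC content.

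The measures were tested on simulated data, after they had first been run on the deposited lists. All 2000 simulated genes given a summit inside the promoter window were recovered (100%), which checks only the assignment, as the same window was used to call them. Of 100 sets of uniformly placed summits, 7% had a promoter share with p under 0.05. With a part of the summits planted in promoters, a promoter share of 41.8% was expected and 42.0% was measured. Gene lists were called in 2% of 50 sets without effect. These sets bound each gene independently, while in the data 442 of 1278 promoter peaks lay in the windows of several genes. The 2% may therefore be too low for the data. With 20% of members bound, 49% of the planted lists were called, and with 40% bound, 100% were called. The planted lists were longer than the tissue marker lists, so these shares do not hold for the latter. For motifs, 2% of 50 sets without effect gave any call, and AGGTCA planted in 10% of summit windows was recovered as an excess of 8.60 percentage points. The simulated motif sets lay at uniform positions. They lacked the GC difference of the data (45.3% at summits, 36.1% in flanks), so this 2% too may be too low. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.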

Results

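The data describe where a tagged nuclear hormone receptor sat on the genome of young Caenorhabditis elegans. NHR-77, fused to the fluorescent protein eGFP, was immunoprecipitated from whole L1 larvae, the first larval stage after hatching, and the bound DNA was sequenced (TF ChIP-seq). The larvae were of mixed sex and of strain OP353, which carries the unc-119(tm4063) mutation and the tagged nhr-77 insertion wgIs353. There was 1 group with 2 biological replicates and no second condition, so the comparisons are between replicates, between kinds of genomic sites and between groups of genes. For each genome build, ce10 and ce11, the deposited peak lists held 1 list per replicate, 1 list from both replicates pooled, and the reproducible peaks chosen from these. The lists give no read totals, so the read depth of each sample is unknown, and intervals below cover counting error only.

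The reproducible set held 2285 peaks in ce11 and 2229 in ce10. The ce11 peaks had a median signal of 92.4, ranging from 58.7 to 809, and 2161 of them were 380 bp wide. Signal is the authors' own value for each peak and is used here only to rank peaks within a list. The replicate lists were relaxed lists that include background, with 21272 peaks for replicate 1 and 24201 for replicate 2.

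Both replicates placed most of their strongest peaks at the same sites. Of the 2285 strongest peaks of replicate 1, 1696 (74.2%) were overlapped by one of the 2285 strongest peaks of replicate 2, against a mean of 1.71% when peaks were placed at random (1000 placements, one-sided permutation p = 0.000999, the smallest they can give). In the other direction, 1711 peaks (74.9%) were overlapped. Over the full relaxed lists, 46.3% of the replicate 1 peaks were overlapped, against 16.5% at random. Among the reproducible regions, 2279 held a peak in both replicate lists, and across these regions the signals of the replicates had a Spearman rho of 0.688 (bootstrap interval 0.663 to 0.714). Regions are not independent replicates, so no p-value is given. The 2285 reproducible peaks were overlapped by the strongest peaks of replicate 1 in 2037 cases (89.1%) and of replicate 2 in 1916 cases (83.9%), and 28 were overlapped by neither. These overlaps are partly built in, since the reproducible set was derived from the replicate lists.

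**Figure D1:**
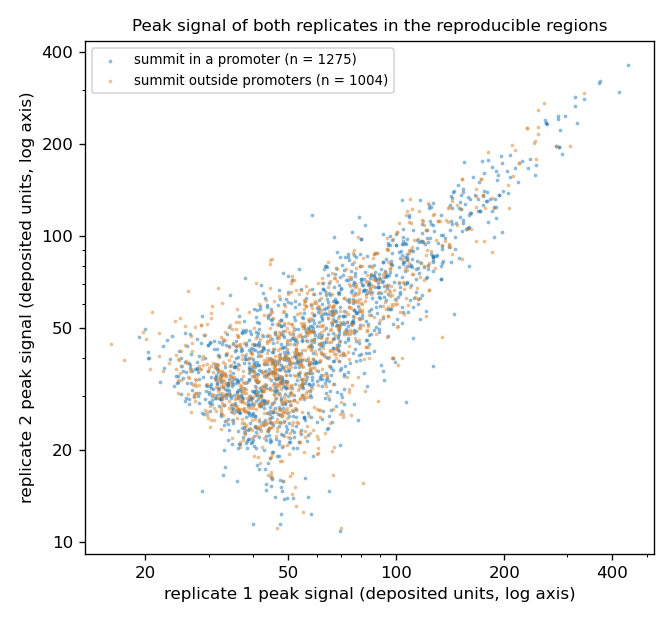
Peak signal in replicate 1 (x axis) against replicate 2 (y axis), in the deposited units on log axes, with 1 point per reproducible region that held a peak in both lists (2279 regions), coloured by whether the summit lay in a promoter. The ranks of the replicates went together (Spearman rho 0.688).

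Several of the strongest peaks lay just upstream of genes for the translation machinery, beside peaks at genes of other kinds. The highest signal (809) belonged to a peak at III:3867430-3867720 (ce11), with its summit at -269 bp from the start of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. Negative distances lie upstream of the gene start. The peak at II:10563435-10563719 (signal 715) lay at -161 bp from cdc-48.1 (WBGene00007352), an AAA ATPase that extracts ubiquitinated proteins. A peak at III:10759109-10759378 (signal 691) lay between tasp-1 (WBGene00010480) and K01G5.10 (WBGene00010481), at -59 and -726 bp. The peak at II:8561300-8561571 (signal 687) lay at -74 bp from iff-2 (WBGene00002065), a homologue of the translation factor eIF5A, and at -861 bp from F54C9.14 (WBGene00175035).

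Further ribosomal protein genes stood among the 25 strongest peaks: rpl-35 (signal 607), rpl-20 (560), rpl-15 (548), rps-12 (512) and rpl-43 (501). Other genes with such a peak in the promoter were puf-9 (WBGene00004245), a Pumilio-family RNA-binding protein (signal 619), R09E12.9 (582), cmtr-1 (526), K12H4.5 (501), egg-5 (492), H41C03.3 (482), nspc-17 (478) and the histone H4 gene his-37 (478). Several strong peaks covered a pair of promoters. The rpl-20 peak was shared with Y17G9B.5, the rpl-15 peak with K11H12.8, the rps-12 peak with ska-3, the rpl-43 peak with Y48B6A.1, and a peak of signal 509 with both nhl-2 and tag-340. All of these summits were intergenic by the annotation. Some lay nearest to the start of a non-coding gene. This was a snoRNA gene for the cmtr-1 peak (-73 bp) and a snRNA gene for the egg-5 (-31 bp) and H41C03.3 (-41 bp) peaks. For the puf-9 peak (56 bp) and the nhl-2 and tag-340 peak (39 bp) it was another ncRNA gene. Which gene such a peak belongs to cannot be told.

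A smaller group of the 25 strongest peaks lay away from any protein-coding promoter, and 6 of these 7 were on chromosome X. The strongest, at X:11093995-11094360 (signal 622), was intergenic, with W02H3.3 (WBGene00195208) as the nearest protein-coding start at 3992 bp. The peak at X:12362977-12363323 (signal 527) had its summit in a 3' UTR, with F19H6.5 nearest at 1780 bp. Those at X:9465720-9466023 (508), X:13700753-13700962 (504), X:4209136-4209409 (478) and X:806601-806793 (471) were intergenic, nearest to ZK899.6 (2525 bp), K02D3.1 (-6040 bp), F20B6.9 (-1793 bp) and gtr-1 (3923 bp). The remaining one, at III:3456299-3456533 (466), lay in a 5' UTR at 2073 bp from the start of C34C12.1. All 25 peaks were overlapped by peaks of both replicates.

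Peaks were concentrated close upstream of genes. Promoters, taken as 1000 bp upstream to 250 bp downstream of protein-coding gene starts, held 1278 of the 2285 summits (55.9%, exact 95% interval 53.9 to 58.0%). Randomly placed summits fell there in 21.9% of cases on average and in at most 24.6% (1000 placements, two-sided permutation p = 0.002, the smallest they can give). The strongest peaks of the replicates gave 55.7% for replicate 1 and 53.4% for replicate 2. The median summit lay at -182 bp from the nearest gene start (-190 and -174 bp in the replicates), and 998 summits (43.7%) lay within 500 bp upstream of one. At the other end, 601 summits (26.3%) were more than 2000 bp from any protein-coding start.

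By annotated feature, 1624 summits (71.1%) were intergenic, against 36.7% of random positions. Introns held 523 summits (22.9%, against 33.9%), 5' UTRs 92 (4.03%, against 1.42%), 3' UTRs 21 (0.919%, against 3.36%) and coding exons 25 (1.09%, against 24.6%). Each of these shares lay outside all 1000 random placements (two-sided permutation p = 0.002). The random positions were uniform along each chromosome and took no account of where short reads can be placed.

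**Figure D2:**
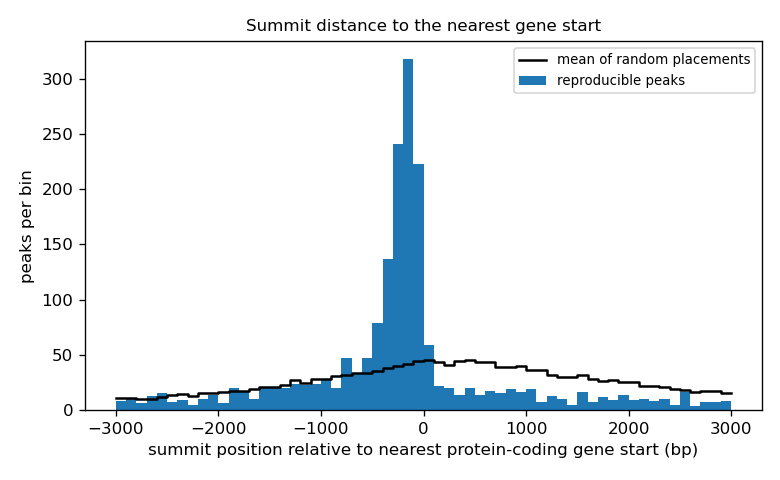
Number of reproducible peaks (bars, ce11) by the position of the summit relative to the nearest protein-coding gene start, in 100-bp bins, with the mean of random placements as a black line. The peaks pile up just upstream of the start, with a median of -182 bp.

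In all, 1717 of 19973 protein-coding genes (8.60%, exact 95% interval 8.21 to 8.99%) had a summit in the promoter. The strongest peaks of replicate 1 gave 1711 genes and those of replicate 2 gave 1635 (mean 1673 ± 53.7, SD), of which 1308 were shared by both replicates. Of the 1278 promoter peaks, 836 lay in 1 promoter and 442 in the windows of several genes. Genes that share a peak in this way cannot be separated, and with each peak given only to its nearest start the count was 1252.

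Genes on chromosomes I and III carried promoter peaks most often and those on V least often. Peaks were present at 347 of 2878 genes on I (12.1%), 319 of 2640 on III (12.1%), 292 of 3449 on II (8.47%), 272 of 3281 on IV (8.29%) and 288 of 4994 on V (5.77%). On the autosomes, genes in the central part of the chromosome, its middle 1 of 3 equal parts, were bound more often than genes on the arms (661 of 6568, 10.1%, against 857 of 10674, 8.03%). The odds ratio of arms to centres was 0.780 (0.700 to 0.869, Fisher's exact test, two-sided p = 5.57e-06), and it was 0.759 and 0.735 with the strongest peaks of replicates 1 and 2.

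Genes on X had a promoter peak in 199 of 2731 cases (7.29%), against 1518 of 17242 autosomal genes (8.80%, odds ratio 0.814, 0.695 to 0.950, Fisher's exact test, two-sided p = 0.00814). This difference depended on how peaks were assigned. With each peak given only to its nearest start the ratio turned to 1.08 (exact p = 0.350), and with the strongest peaks of replicate 1 alone the difference missed the threshold (odds ratio 0.863, p = 0.0558), as it did with the 1143 strongest reproducible peaks (0.816, p = 0.0513). X held 420 peaks, of which 186 (44.3%) lay in promoters, while the share was 54.7 to 64.4% on each autosome. X also had fewer protein-coding genes per Mb than any autosome (2731 genes in 17.7 Mb), and no random share was computed by chromosome. Whether gene density accounts for the lower promoter share on X was therefore not tested.

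**Figure D3:**
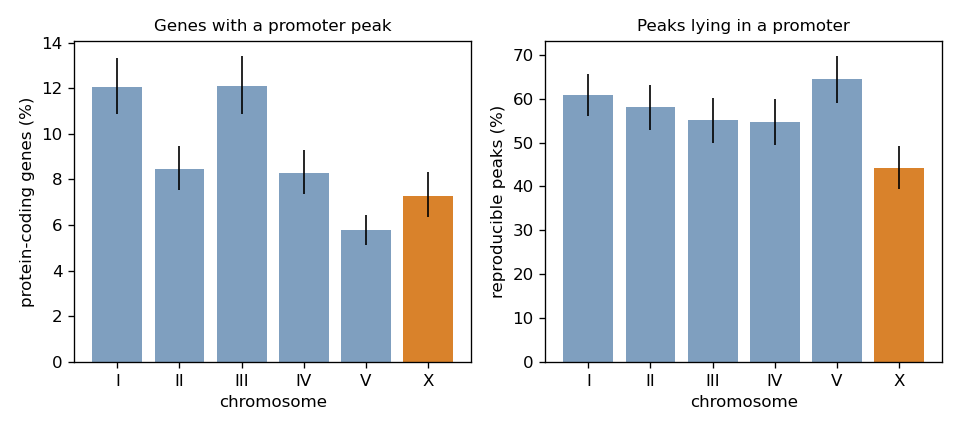
Left, percent of protein-coding genes with a promoter peak on each chromosome, and right, percent of the reproducible peaks of each chromosome that lay in a promoter, with exact 95% intervals as error bars and X in orange. Chromosomes I and III had the highest share of bound genes (12.1% each), and X had the lowest share of peaks in promoters (44.3%).

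Genes for protein synthesis, energy production and other functions of most cells were bound far more often than other genes. Of 30 gene lists fixed before the data were examined, 13 were bound more often than the remaining protein-coding genes and 5 less often (Fisher's exact test per list, two-sided, Benjamini-Hochberg over the 30 lists). Lists were defined by gene name, so only genes with a name in the annotation could be members. Such named genes were bound more often (11.2%) than unnamed ones (5.45%). Against named genes only, 12 lists were bound more often and 8 less often. The odds ratio was then 31.4 for ribosomal proteins and 2.17 for mitochondrial ribosomal proteins. Values below are against all protein-coding genes unless stated. Ribosomal proteins stood first, with 64 of 81 genes bound (79.0%, exact 95% interval 68.5 to 87.3%), against 8.31% of other genes (odds ratio 41.5, 24.0 to 75.8, adjusted exact p = 1.91e-51). The strongest peaks of each replicate also covered 80.2% of this list. Its strongest members were rpl-3, rpl-35 and rpl-20. With each peak given only to its nearest start the list fell to 37 of 81 genes (45.7%, odds ratio 12.9), and rpl-20, rps-12 and rpl-43 lost their peaks to neighbours.

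Splicing factors were bound at 20 of 38 genes (52.6%, odds ratio 11.9, adjusted exact p = 3.23e-11). They included snr-4, a core spliceosomal Sm protein (signal 282), prp-19 (198) and prp-8, the central protein of the spliceosome (169). With nearest starts only, 10 of 38 remained (26.3%, odds ratio 5.37). Genes of the respiratory chain and ATP synthase followed with 21 of 46 (45.7%, odds ratio 9.03, adjusted exact p = 2.35e-10), led by the cytochrome c oxidase subunits cox-5A (399) and cox-5B (381) and the ATP synthase subunit atp-1 (298). Translation factors were bound at 16 of 38 genes (42.1%, odds ratio 7.79, adjusted exact p = 1.48e-07), with iff-2, eif-3.B (381) and the elongation factor eef-1A.2 (338) highest. Proteasome subunits were bound at 12 of 33 genes (36.4%, odds ratio 6.11, adjusted exact p = 3.34e-05), among them rpn-3 (285), rpn-11 (138) and rpt-2 (137).

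The vacuolar ATPase, the proton pump of acidic organelles, had 7 of 20 subunit genes bound (35.0%, odds ratio 5.74, adjusted exact p = 0.00195), with vha-8 (350), vha-1 (209) and vha-12 (195) highest. DNA replication and cell cycle genes were bound at 17 of 51 (33.3%, odds ratio 5.36, adjusted exact p = 2.63e-06), led by cdc-48.1, cdk-7 (233) and cdk-5 (156). CDC-48.1 has roles well beyond the cell cycle, and CDK-5 acts mainly in neurons. Chaperones were bound at 18 of 59 (30.5%, odds ratio 4.71, adjusted exact p = 4.76e-06), with the Hsp70 proteins hsp-1 (356) and hsp-3 (302) and with hsp-110 (285), whose peak also lay in the rpn-3 promoter. RNA polymerase and general transcription factors (9 of 37, 24.3%, odds ratio 3.43, adjusted exact p = 0.00640) included rpb-11 (312), taf-4 (193) and taf-12 (147). Vesicle traffic genes (19 of 79, 24.1%, odds ratio 3.39, adjusted exact p = 8.17e-05) included sec-61.G (312) and sec-61.B (254), subunits of the translocon of the endoplasmic reticulum, and vps-51 (254). Mitochondrial ribosomal proteins (15 of 70, 21.4%, odds ratio 2.92, adjusted exact p = 0.00174) were led by mrps-7 (234.9), mrpl-37 (213) and mrpl-55 (210).

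Aminoacyl-tRNA synthetases (7 of 32, 21.9%, odds ratio 2.98, adjusted exact p = 0.0284), with mars-1 (133), vars-1 (93.7) and kars-1 (81.1), were called under few settings. The call was lost with the strongest peaks of replicate 2 alone (adjusted exact p = 0.259), with the 1143 strongest peaks (0.793) and under 4 other alternatives (adjusted p from 0.0745 to 0.114). Body wall muscle markers were the only tissue list called (6 of 20, odds ratio 4.57, adjusted exact p = 0.00953). Their strongest members were the actins act-1 (93.4) and act-2 (89.8) and the myosin light chain mlc-1 (79.2). This call too was lost with the 1143 strongest peaks (adjusted exact p = 0.772) and with replicate 2 alone (4 of 20 genes, adjusted exact p = 0.126).

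Chemoreceptors, immune effectors, F-box genes, neuropeptides and channels seldom had a promoter peak. Chemoreceptors, the receptors of sensory neurons, were bound at 8 of 1314 genes (0.609%, odds ratio 0.0608, adjusted exact p = 4.69e-40), the strongest being srh-16 (142), sri-5 (133) and srh-269 (90.9). Immune effectors were bound at 3 of 346 (0.867%, odds ratio 0.0914, adjusted exact p = 2.14e-09), namely fipr-17 (144), clec-126 (122) and clec-57 (61.5). F-box genes were bound at 8 of 322 (2.48%, odds ratio 0.267, adjusted exact p = 3.65e-05), among them fbxb-58 (315), fbxa-90 (227) and fbxb-85 (200). Neuropeptides and insulins were bound at 2 of 140 genes (1.43%, odds ratio 0.153, adjusted exact p = 0.00170), ins-39 (323) and nlp-4 (69.4). Ligand-gated and potassium channels were bound at 2 of 134 (1.49%, odds ratio 0.160, adjusted exact p = 0.00195), glr-6 (173) and twk-10 (74.1).

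The receptor's own family did not stand apart. Nuclear hormone receptors were bound at 24 of 274 genes (8.76%, odds ratio 1.02, 0.640 to 1.56, adjusted exact p = 1.00), and the strongest were nhr-238 (309), nhr-237 (298), the fat metabolism regulator nhr-49 (191), nhr-48 (169) and nhr-57 (162). Nor did lipid metabolism genes (6 of 96, led by ech-5, odds ratio 0.708, adjusted exact p = 0.727), detoxification enzymes (11 of 188, gst-27, 0.659, 0.323), histones (7 of 72, his-37, 1.15, 0.794), or homeobox genes (3 of 79, ceh-38, 0.419, 0.226) pass the test. Cuticle collagens were bound at 7 of 169 genes, with col-38 highest (odds ratio 0.457, adjusted exact p = 0.0594). Lipid genes were called less often bound with the 1143 strongest peaks (0 of 96, adjusted exact p = 0.0455), and homeobox (0.0467) and detoxification genes (0.0318) against named genes only. Collagens passed the threshold as less often bound under 4 alternatives, replicate 2 alone among them (odds ratio 0.270, adjusted exact p = 0.00516).

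Markers of the intestine (1 of 19, erm-1), pharynx (1 of 16, myo-1), germline (1 of 20, mes-2), neurons (2 of 20, with ric-19 highest) and epidermis (0 of 20), and the major sperm proteins (0 of 31), did not pass either. These lists are short. For the epidermis list the exact interval reached 16.8% and for the sperm list 11.2%, so a share like that of all genes was not excluded for them.

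Against genes whose upstream neighbour lay at least 1000 bp away, 9 lists remained above the threshold in the higher direction and 4 in the lower. This background holds 9597 genes and few members of each list. Calls were lost for chaperones (3 of 16, odds ratio 3.66, adjusted exact p = 0.116), proteasome subunits (1 of 3, 7.91, 0.240), splicing factors (2 of 6, 7.92, 0.0903) and F-box genes (3 of 122, 0.395, 0.191), so the lost calls do not show that the differences went away. Odds ratios rose for the respiratory chain (5 of 7, 39.8), vacuolar ATPase (4 of 7, 21.2), mitochondrial ribosomal proteins (4 of 8, 15.9), translation factors (3 of 6, 15.9), vesicle traffic (7 of 18, 10.2) and the polymerase list (3 of 10, 6.80). Histones, not called in the main setting, rose to 10.6 (2 of 5) without passing the threshold (adjusted exact p = 0.0671). Chaperones also missed the threshold with each peak given only to its nearest start (odds ratio 2.35, adjusted exact p = 0.0502), though their ratio was 8.36 with the 1143 strongest peaks, and the polymerase list missed it with the wide promoter window (0.0501). With replicate 2 alone the odds ratio was 9.42 for proteasome subunits and 0.162 for immune effectors, and with replicate 1 alone it was 5.15 for the polymerase list. Chemoreceptors ranged from 0.0289 with the 1143 strongest peaks to 0.0954 with the wide window, which also gave 0.301 for channels, and neuropeptides had 0.0968 with the narrow window.

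**Figure D4:**
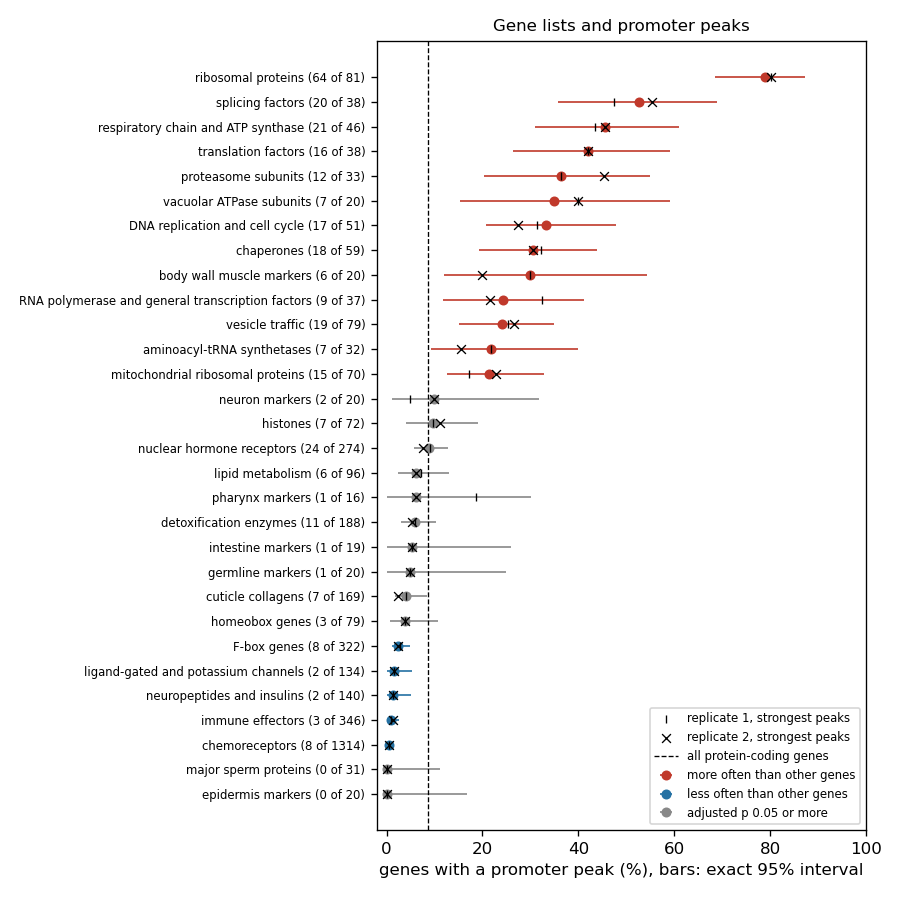
Percent of the genes of each list that had a promoter peak (circles, reproducible peaks, with exact 95% intervals), the same share from the strongest peaks of replicate 1 (vertical ticks) and replicate 2 (crosses), and the share over all protein-coding genes (dashed line, 8.60%). Ribosomal proteins lie at 79.0% and chemoreceptors at 0.609%.

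Genes for small structural RNAs were bound more often than protein-coding genes. Peaks lay in the promoter windows of 189 of 612 tRNA genes (30.9%, odds ratio 4.75, 3.95 to 5.69, adjusted exact p = 1.01e-52), 117 of 346 snoRNA genes (33.8%, odds ratio 5.43, 4.29 to 6.86, adjusted exact p = 4.92e-38) and 24 of 129 snRNA genes (18.6%, odds ratio 2.43, 1.49 to 3.83, adjusted exact p = 0.000755). The tRNA share was 30.4% and 25.2% in the strongest peaks of replicates 1 and 2, and the snoRNA share 34.4% and 31.5%. With the 1143 strongest peaks the odds ratio was lower for tRNA genes (2.42) and higher for snRNA genes (3.95). Counting only peaks outside protein-coding promoters, an alternative added after the data were seen, left 147 tRNA genes (24.0%), 60 snoRNA genes (17.3%) and 13 snRNA genes (10.1%). The snRNA interval was then 5.48 to 16.6%. Protein-coding genes cannot be bound by these peaks by definition, and their 8.60% counts all peaks, so it is no like benchmark. Whether an excess at snRNA genes remained there was therefore not decided. piRNA genes (193 of 15363, 1.26%, odds ratio 0.135, adjusted exact p = 1.89e-235) and pseudogenes (15 of 2128, 0.705%, odds ratio 0.0755, adjusted exact p = 8.60e-57) were bound less often.

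No call was made for miRNA precursors (18 of 261, 6.90%), lincRNA (15 of 194, 7.73%), other ncRNA (646 of 7764, 8.32%), antisense RNA (6 of 100) or rRNA genes (0 of 20). The piRNA odds ratio was 0.0647 with the narrow and 0.218 with the wide window. With the narrow window, other ncRNA (odds ratio 0.769, adjusted exact p = 7.27e-06) and antisense RNA (0.137, adjusted exact p = 0.0214) were bound less often. Many tRNA genes exist in near-identical copies, and the lists do not show how reads that match several copies were treated.

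Summits were rich in GAGA repeats and in the CTGCGTCT element and poor in GATA sites. GAGAGAG occurred in 460 of 2285 windows of 150 bp at summits (20.1%) and in 62 windows 500 bp away (2.71%, exact McNemar test, two-sided, Benjamini-Hochberg over 12 motifs, adjusted exact p = 3.28e-82). CTGCGTCT occurred in 305 summit windows (13.3%) and 16 flank windows (0.700%, adjusted exact p = 1.65e-73). The E2F-type site (6.21% against 2.19%, adjusted exact p = 1.27e-11), the GC box (8.71% against 2.93%, adjusted exact p = 1.14e-16) and the E-box (5.03% against 2.28%, adjusted exact p = 1.50e-06) were also more frequent at summits. The GATA site, bound by regulators of intestine and epidermis, was less frequent (6.74% against 14.7%, adjusted exact p = 1.64e-17), and so was the CCAAT box (22.6% against 26.0%, adjusted exact p = 0.0124). In 100-bp windows the differences were smaller for each of these motifs, and in 300-bp windows they were larger. For GATA sites they were -5.12 and -9.85 percentage points, and for GC boxes 3.63 and 8.40 percentage points.

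The sequence AGGTCA, the core element to which many nuclear receptors bind, was as frequent at summits as beside them (93 windows, 4.07%, against 94 windows, 4.11%, adjusted exact p = 1.00). Its direct repeat with a 1-bp spacer was in 0 windows of either kind, and the HNF4-type site (0.700% against 0.306%, adjusted exact p = 0.140), the forkhead site (6.35% against 5.25%, adjusted exact p = 0.167) and the AP-1 site (1.44% against 1.58%, adjusted exact p = 0.965) did not pass. Summit windows had a mean GC content of 45.3%, against 36.1% in the flanks. When the 1278 promoter summits were set against windows of unbound promoters matched on position and GC content, GAGAGAG (odds ratio 2.44, adjusted exact p = 6.20e-10), CTGCGTCT (4.63, 1.43e-18) and the E2F-type site (1.58, 0.0242) were still more frequent, and the forkhead site passed as well (1.62, 0.0325), as it did against flanks with replicate 1 alone (adjusted exact p = 0.0157). The GC box (1.14, adjusted exact p = 0.630) and the E-box (1.02, adjusted exact p = 1.00) no longer differed beyond the threshold, while GATA sites (0.490, 2.03e-06) and CCAAT boxes (0.736, 0.00247) were again less frequent. The CCAAT difference missed the threshold with the 1143 strongest peaks (adjusted exact p = 0.378).

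**Figure D5:**
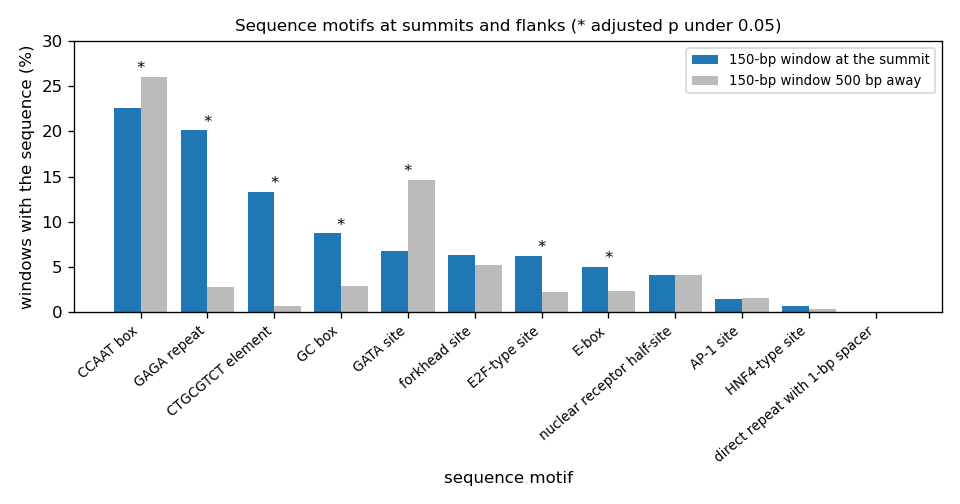
Percent of 150-bp windows that held each sequence motif, at the summits of the reproducible peaks (blue) and 500 bp away on a side drawn at random (grey), with an asterisk where the adjusted p was under 0.05. GAGA repeats rose from 2.71% in the flanks to 20.1% at summits, and GATA sites fell from 14.7% to 6.74%.

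The nhr-77 and unc-119 loci carried no excess of peaks within 20 kb. They were examined because the strain carries a tagged nhr-77 insertion in an unc-119 background. Extra copies of these loci could raise the signal there. The nhr-77 gene (WBGene00003667, I:12384277-12385731, minus strand) had 0 reproducible peaks within 20 kb, where the median protein-coding gene had 1 and 43.7% of genes had 0. It also had 0 peaks of the pooled relaxed list within 20 kb, where the median was 5 and 2.80% of genes had 0, and 3 and 4 peaks in the lists of replicates 1 and 2, where the medians were 9 and 10. The unc-119 gene (WBGene00006843, III:10902641-10908935, plus strand) had 0 reproducible and 4 pooled peaks within 20 kb, where the medians were 1 and 5. Within 10 kb it had 4 pooled peaks, where the median was 3 and 63.2% of genes had fewer. Neither gene had a reproducible peak in its promoter.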

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

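Of 86 values of the main results under alternatives, 72 were labelled unchanged, by broad rules. A share or overlap only had to stay above random placement past the threshold, and a count could move by a moderate factor. A replicate overlap of 46.3% over the full lists and 9 lists in place of 13 thus counted as unchanged. So did a promoter share of 46.6% with the narrow window, where random placement gave 11.1%. The alternatives chosen only after the result was seen were promoters of all gene classes except piRNA (promoter share 73.1%), lists stratified by promoter GC content (6.58), and small RNA classes outside promoters, which gave counts without a test. The promoter share was 46.6 to 67.0% over the alternatives set beforehand. Random placement gave 21.9% in the main setting, 39.4% with the wide window and 31.1% with all gene classes except piRNA. In proportion to random placement, the share was thus highest with the narrow window and lowest with the wide one (67.0%). The arms against centres ratio was 0.735 to 0.844, and both results passed the threshold in each alternative. With the 1143 strongest peaks, bound genes fell to 936, as fewer peaks were used, the X ratio was 0.816 and 1 motif in place of 2 was less frequent. The X ratio was 0.771 to 0.863 with a replicate left out and 1.08 with nearest starts. Signals matched by nearest summit had a rho of 0.661. Against named genes 8 lists were bound less often, and with the narrow window 4 gene classes were. The percent of genes with as few reproducible peaks nearby was 63.1 (strongest peaks), 61.3 (10 kb) and 24.1 (40 kb) for nhr-77, and 63.1, 61.3 and 48.6 for unc-119. Other reversals were in results called neither in the main setting nor in the reversed one. Odds ratios were, with the strongest peaks, 0 for neuron, 1.07 for germline markers and 1.07 for miRNA. With a replicate left out they ranged 0.562 to 1.25 for neuron markers, 0.930 to 1.07 for nuclear receptors, 0.748 to 2.47 for pharynx markers and 0.982 to 1.29 for miRNA. With the narrow window nuclear receptors gave 0.952, and with the wide one 0.994, pharynx 2.60, histones 0.839, lipid genes 1.11 and miRNA 1.25. Against named genes neuron markers gave 0.879, nuclear receptors 0.755 and histones 0.852, and against genes with a distant neighbour pharynx 1.32, lipid 1.13 and intestine 1.13. Differences in motif frequency, in percentage points, were -0.875 (forkhead) and 0.262 (AP-1) with the strongest peaks, -0.175 to 0.306 (AP-1) with a replicate left out, 0.235 (AP-1) against matched promoters, and 0.219 and 0.788 (AGGTCA) with 100-bp and 300-bp windows. The cause of these changes was not tested. Of 85 named bound genes, 84 and 83 were bound without replicate 1 and without replicate 2, 69 with the narrow window, 70 with nearest starts, 74 with the strongest peaks and 85 with the wide window. No paired analysis was possible because there was only 1 group. Read depth is unknown, so how many weaker sites were missed cannot be told.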

Other observations

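Apart from the AGGTCA element against matched windows, which was set beforehand, the comparisons in this part were chosen after the main results were seen. For the AGGTCA element, the recruitment motif and the control copies, what each explanation would show was written only after the result itself was seen, and the measure for the control copies was replaced after a first version. Peaks at small RNA genes made up a part of the data of their own. Summits within 250 bp of a tRNA, snoRNA or snRNA gene start numbered 191 outside protein-coding promoters (8.36% of all peaks). Among tRNA genes, those with an identical copy elsewhere were bound at 160 of 469 (34.1%) and single-copy ones at 29 of 143 (20.3%, odds ratio 2.03, 1.28 to 3.31, Fisher's exact test, two-sided p = 0.00185). At small RNA peaks outside promoters a median of 84.3% of 36-bp words occurred once in the genome, and only 45.0% of windows exceeded 90%, so reads shared between copies are not excluded as a cause. X-linked tRNA genes did not differ detectably from autosomal ones (86 of 276, 31.2%, against 103 of 336, 30.7%, exact p = 0.930). The most enriched 8-bp word in the small RNA peaks was GGGTTCGA, which overlaps the internal promoter of tRNA genes (39 of 191 windows, 20.4%). The genes sls-2.4 and sls-2.1, which encode SL2 spliced-leader RNAs, lay nearest to the peaks that ranked 19 and 20, at -31 and -41 bp.

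In promoters, the 8-bp words most enriched at summits included AGACGCAG, the reverse complement of the CTGCGTCT element (155 of 1278 windows, 12.1%, against 9 and 7 in the flanks), AAACGCGC (111 windows, 8.69%, against 2 and 2) and GCGCCAGC (71 windows, 5.56%, against 0 and 2). AGACGCAG was also frequent at the 644 autosomal peaks away from promoters and small RNA genes (133 windows, 20.7%). On X, 44.3% of peaks lay in promoters, against 58.6% on the autosomes (186 of 420 against 1092 of 1865, odds ratio 0.563, 0.452 to 0.700, exact p = 1.22e-07). The strongest peaks of replicates 1 and 2 gave 44.4% and 41.2% for X. Neither this comparison nor that of strong peaks below took account of the lower gene density of X.

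The 13 lists bound more often held 231 bound genes of 604 (38.2%), against 7.67% of other genes (odds ratio 7.45), a size that is inflated because the lists were pooled for being bound more often. Stratified by promoter GC content (mean 36.3% in the lists, 35.2% in other genes) the ratio was 6.58 (5.50 to 7.86). With each peak given only to its nearest start it was 5.53 (4.52 to 6.73). Neither the GC content of whole promoters nor neighbouring genes accounted for the whole difference in these lists. Pooling lists for being bound more often also favoured a ratio above 1 in each case. The strata did not use GC content at the summits (45.3%, against 36.1% in flanks), so a local effect was not tested. Over all 1278 promoter summits, AGGTCA had an odds ratio of 0.686 (0.456 to 1.02) against matched windows. This argues against an excess of that exact sequence over promoter summits as a whole. The genes of these lists were not examined apart, and other receptor elements were not covered. The comparison therefore does not decide how the receptor was held at these promoters. An open explanation is that immunoprecipitation recovers highly transcribed, open promoters whichever protein is tagged. No untagged or other tagged strain was analysed here, and apart from AGGTCA over all promoter summits no biological explanation was tested.

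Among the 228 strongest peaks, those away from promoters and small RNA genes were 26 of 48 on X (54.2%) and 43 of 180 on autosomes (23.9%, odds ratio 3.74, 1.84 to 7.71, exact p = 0.000148), a set that includes the peaks that prompted the comparison, while over all peaks they were 172 of 420 (41.0%) and 644 of 1865 (34.5%, odds ratio 1.31, exact p = 0.0153). Repeated sequence is argued against, since in the 26 X windows a median of 100% of 36-bp words (lowest window 100%) occurred once in the genome. Matches at 11 or more positions to TCGCGCAGGGAG, a motif of sites that recruit the dosage compensation complex to X, lay in reproducible peaks at 15 of 32 X sites and 0 of 37 autosomal sites (Fisher's exact test, two-sided p = 9.98e-07), in the strongest peaks of replicates 1 and 2 at 16 and 18 X sites and 1 and 0 autosomal sites, and in pooled peaks at 19 X and 6 autosomal sites (odds ratio 7.30). The 15 sites fell in 12 peaks, so not all are independent. Among these peaks were X:11093995-11094360, the peak in the nspc-17 promoter, and X:8036232-8036667 near xol-1, the master switch of sex determination. As a hypothesis, some of the 26 strong X peaks away from promoters may mark recruitment sites. Of them, 9 of 26 held a match, against 0 of 43 such autosomal peaks (Fisher's exact test, p = 5.51e-05). The others of the 26 held none, and whether the tagged receptor or the openness of such sites gives the signal was not tested.

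The nhr-77 locus lay in an interval of 55.7 kb without a pooled peak (I:12363774-12419489), where the median gap was 3.98 kb and 66 of 13494 gaps were as long. A low density of peaks in this region could not be settled: 28 of 412 genes within 1 Mb (6.80%) also had 0 pooled peaks within 20 kb, and 5 of 228 gaps there were as long. Extra copies of the locus in the control could lower the peaks called here, and the replicate lists, with at most 4 peaks near the gene against medians of 9 and 10, do not exclude this. The control was not analysed here, so these explanations cannot be told apart.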
